A study of Homo sapiens with 6 samples.

How the data were processed

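CUT&Tag libraries from HepG2 cells were analysed for 3 targets, ENO1, H4K12la and HDAC1, with 2 replicates each, grouped and numbered by their titles in the labels. Per the submitters' processing notes, the tools were FastQC, Bowtie2, MACS2 and deepTools and the genome build was hg38; versions, settings and order are not given in the sources used here. The deposited files are MACS2 narrow peak lists, 1 for each library, so peaks were called per sample. Whether a control library was used in calling is not given in the sources used here, and no control library was analysed here. In each deposited list, the fold enrichment of a peak is a ratio of summit signal over the peak caller's background within that library, with no scaling between libraries. The authors' lists also give the -log10 of the p value and of the q value for each peak, and a score that equals the whole part of 10 times the -log10 q. The lowest -log10 q lies just above 2 in each list, so the deposited lists end at a q value of 0.01. Read counts and depth were not used here, so absence of a peak is not absence of signal, and the number of peaks (1395 to 7773 per library over all sequences) limits what each list can show. Intervals cover counting error only.

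Peaks on the 22 numbered chromosomes, X and Y were used. Peaks sharing at least 1 bp were taken as overlapping, and reproducible regions were the merged peaks of a target that overlapped between both replicates. Genes came from the RefSeq gene table of GRCh38 patch 14, whose build is that of the peak lists. The table used here gives neither strand nor transcript starts, so promoters, named in the design, were replaced by windows of 1 kb around both annotated ends of 19862 protein-coding genes. Of the genes over 10 kb long with such a peak, 98.7% to 99.2% had it at 1 end only in the H4K12la and HDAC1 libraries. Gene entries on unplaced or alternate sequences that carry a chromosome's name (718, of which 171 protein-coding) were left out, since their coordinates belong to other sequences; they were told by the first drop in position within a chromosome of the table. A gene counted as occupied when both replicates had a peak in its windows.

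Replicate overlap, gene-end shares and overlap of regions were set against 1000 random placements of the same regions on their own chromosomes (one-sided permutation tests). For gene-end shares the side was that of the observed difference, so those p values are smaller than a test of both directions would give. Unsequenced gaps were not excluded from these placements. Shares over 50 kb from genes and in the longest gene-free stretch of each chromosome were also averaged over 100 random sets. Similarity of libraries was measured by the Jaccard index and tested over the 15 ways to pair them. Occupied genes were compared between targets, and between each of 29 gene lists and other protein-coding genes, by two-sided Fisher's exact tests with conditional odds ratios and exact 95% intervals, and lists were adjusted by Benjamini-Hochberg over 87 tests. The lists covered glycolysis and lactate, the citric acid cycle, oxidative phosphorylation, cytosolic and mitochondrial ribosomal proteins, proteasome subunits, translation initiation factors, aminoacyl-tRNA synthetases, splicing factors, replication-dependent histones, cell cycle and DNA replication, immediate early genes and MYC, HDAC1 complexes, lactyl and acetyl enzymes of histones, hypoxia, the unfolded protein and heat shock response, p53 targets, autophagy and lysosome, ferroptosis and redox, secreted liver proteins, liver transcription factors, liver metabolic enzymes, cholesterol and fatty acid synthesis, Wnt targets, extracellular matrix and mesenchymal genes, blood and immune cells, neurons and muscle, olfactory receptors and keratin-associated proteins. Median fold enrichment of H4K12la peaks with and without overlap of ENO1 or HDAC1 regions was compared within each H4K12la list by a two-sided permutation test with 100000 resamples. Strata of gene length and of gene density (protein-coding neighbours within 500 kb) were 5 groups of about equal size, combined by Cochran-Mantel-Haenszel chi-square tests without continuity correction. Genes carrying only H4K12la or only HDAC1 whose windows touched a common peak region of any library, directly or through another gene, were also reduced to 1 gene.

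Genes were named by a fixed rule: for each target the 10 with the highest value of the lower of both replicates' fold enrichments, up to 10 with the best mean rank among genes carrying all 3 targets (6 did), up to 4 occupied members of each list, always ENO1, HDAC1, LDHA and MYC, and for each target the 3 strongest regions away from gene ends. Some list members that the rule selects were left unnamed.

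The scripts were tested on simulated data: planted replicate overlaps were recovered, and of simulated lists with a planted odds ratio of 6, 94.0% were called for H4K12la and 88.4% for HDAC1 over 19862 genes. With a planted odds ratio of 3 the calls were 52.8% and 46.9%, and with 1 they were 2.73% and 0.939%. Lists planted with 6, 3 and 1 numbered 200, 197 and 183 for H4K12la and 190, 177 and 213 for HDAC1. Most simulated lists thus held a difference, whereas 5 real lists passed for H4K12la, 7 for HDAC1 and 0 for ENO1. Benjamini-Hochberg adjustment is more lenient when more tests hold a difference. The simulated call rates may therefore overstate the power of the reported list tests. Alternatives tried were a stricter q, a 50% reciprocal overlap, all sequences, equal numbers of strongest peaks (1189 per library), peaks of either replicate, single replicates, windows of 500 and 2500 bp, a background of genes with a peak in any library, and strata by replicate number; those added after the data were seen are named where they appear. Motif tests and alternatives needing sequence or transcript starts were not run, since no genome sequence was used here. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9.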

Results

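Chromatin occupancy was mapped by CUT&Tag, in which an antibody directs a transposase to cut and tag the DNA around its target, in HepG2, an established human hepatocellular carcinoma line. The antibodies recognised ENO1, the glycolytic enzyme enolase 1; HDAC1, a histone deacetylase; or H4K12la, histone H4 lactylated at lysine 12. Each of the 3 targets had 2 replicate libraries, 6 in all, and the labels do not say that replicates came from separate cultures, so the spread between them may be technical. On the 24 chromosomes the ENO1 lists held 1592 and 1189 peaks, the H4K12la lists 5459 and 7568, and the HDAC1 lists 5727 and 4567. Median fold enrichment over background, the peak caller's own value and used here only within a list, was 5.76 and 5.78 for ENO1, 4.01 and 4.04 for H4K12la, and 4.67 and 4.88 for HDAC1. Only peak lists were used, so sequencing depth is unknown and a gene without a peak may hold signal below the calling threshold. The gene lists and tests below were fixed before the data were examined, except where stated.

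The series was designed to learn how ENO1 and HDAC1 relate to histone lactylation and transcription, and the location of each target's peaks was compared. H4K12la and HDAC1 peaks gathered at the ends of protein-coding genes, whereas ENO1 peaks lay mostly over 50 kb from protein-coding genes. Of the 3561 H4K12la regions found in both replicates, 1686 (47.3%, Wilson 95% interval 45.7 to 49.0) lay within 1 kb of a gene end, as did 1271 of 3089 HDAC1 regions (41.1%, 39.4 to 42.9). Of the 768 ENO1 regions only 15 did (1.95%, 1.19 to 3.20). In contrast, 74.2% of ENO1 regions lay over 50 kb from any protein-coding gene, against 16.6% of H4K12la and 30.5% of HDAC1 regions; random placement gave 41.1%, 37.7% and 36.8% for ENO1, H4K12la and HDAC1. The longest gene-free stretch of each chromosome alone held 46.4% of the ENO1 regions, 6.74% of the H4K12la regions and 18.6% of the HDAC1 regions, all above their random means of 9.0%, 4.19% and 5.32%, a comparison without a test. By library, the gene-end share was 1.94% ± 0.365 for ENO1, 42.4% ± 2.01 for H4K12la and 37.8% ± 4.47 for HDAC1 (SD, n = 2). Randomly placed regions of the same sizes fell at gene ends in 3.54%, 3.46% and 3.79% of cases for ENO1, H4K12la and HDAC1. H4K12la and HDAC1 exceeded this (one-sided permutation p = 0.001 each, the smallest that 1000 placements can give). ENO1 lay below it (one-sided permutation p = 0.006, with the side set by the observed direction). Without the regions over 50 kb from genes, an alternative added after the data were seen, the ENO1 share was 7.58%. It lay above its random placements (permutation p = 0.018), but these still covered whole chromosomes. Leaving out far regions raises the observed share alone, so this test cannot show gathering at gene ends.

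**Figure D1:**
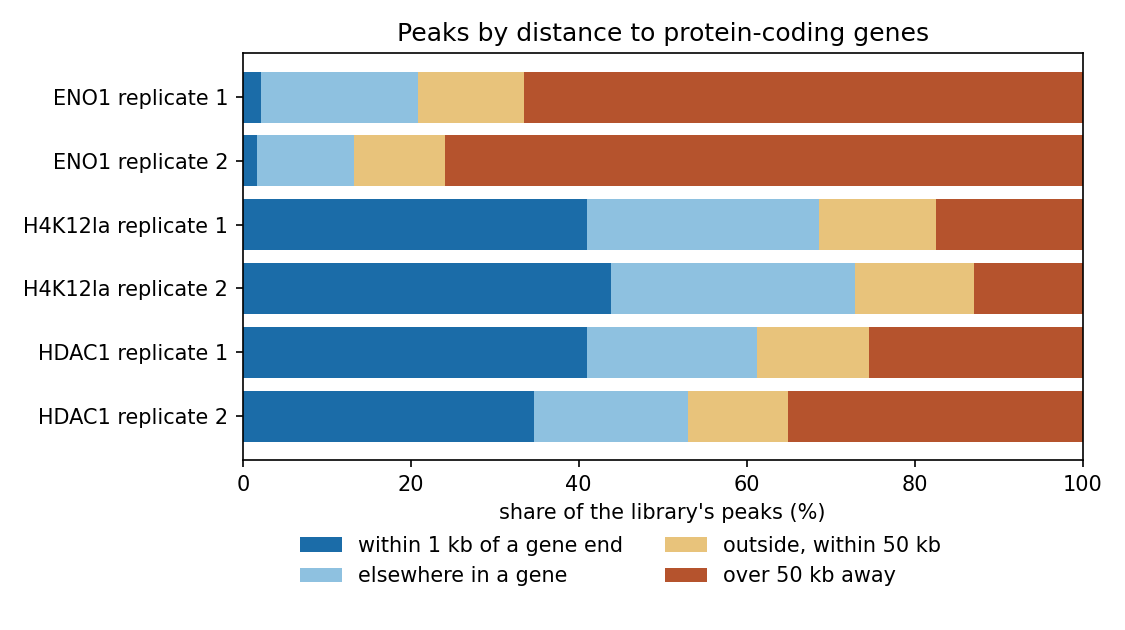
Share of each library's peaks (%, horizontal axis) by distance to protein-coding genes, with 1 bar for each of the 6 libraries. The gene-end part is 2.20% and 1.68% in the ENO1 libraries and 34.7% to 43.8% in the H4K12la and HDAC1 libraries, while peaks over 50 kb from a gene make up 66.5% and 75.9% of the ENO1 lists.

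The strongest regions away from gene ends were the same places for several targets. A region on chromosome 17 (25920036 to 25920475), 1374 kb from WSB1, the nearest protein-coding gene, led the ENO1 list at 33.2-fold and 25.7-fold in replicates 1 and 2. H4K12la reached 25.9-fold and 27.1-fold there, and HDAC1 29.8-fold and 33.5-fold. A chromosome 3 region (93470362 to 93470867), 402 kb from PROS1, which encodes the anticoagulant protein S, reached 31.0-fold and 24.4-fold for ENO1, 25.3-fold and 26.2-fold for H4K12la, and 27.5-fold and 29.5-fold for HDAC1. Another chromosome 17 region (22521207 to 22521882), 817 kb from KCNJ18, a potassium channel gene, reached 32.1-fold and 24.2-fold for ENO1 and was also among the 3 strongest for HDAC1 at 26.5-fold and 28.5-fold. Also among the 3 strongest for H4K12la, a region (chromosome 2, 222866190 to 222866896; 23.9-fold and 25.2-fold) lay within ACSL3, a long-chain acyl-CoA synthetase gene. All of these places held a peak in all 6 libraries.

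In shared base pairs, lists of the same target had more in common than lists of different targets, although 428 of the 768 ENO1 regions (55.7%) overlapped a peak in all 4 H4K12la and HDAC1 libraries and 28 (3.65%) overlapped none. Of the 1189 peaks in the smaller ENO1 list, 768 (64.6%) overlapped a peak of the other replicate, as did 3578 of 5459 H4K12la peaks (65.5%) and 3101 of 4567 HDAC1 peaks (67.9%). Counted by peaks, ENO1 overlapped the longer HDAC1 lists more often than its own replicate: ENO1 replicate 1 at 61.7% and 65.2% against 49.1%, and replicate 2 at 73.1% and 74.5% against 64.6%. Random placement gave means of 0.0908%, 0.356% and 0.262% (one-sided permutation p = 0.001 each, the smallest possible). Fold enrichment of shared regions ranked alike in both replicates, with Spearman's rho of 0.897 for ENO1, 0.726 for H4K12la and 0.802 for HDAC1 across regions, which are not independent replicates. At gene ends rho was lower, 0.583 for H4K12la over 1686 regions and 0.695 for HDAC1 over 1271. The Jaccard index, the shared base pairs as a part of all base pairs covered, was 0.411 for the ENO1 replicates, 0.320 for H4K12la and 0.389 for HDAC1. Between targets it ranged from 0.0732 to 0.212 over 12 pairs. The mean over same-target pairs, 0.373, was the highest of the 15 ways to pair the libraries, whose mean was 0.197 (exact permutation p = 0.0667, one-sided, the smallest this design allows, so it cannot pass 0.05).

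**Figure D2:**
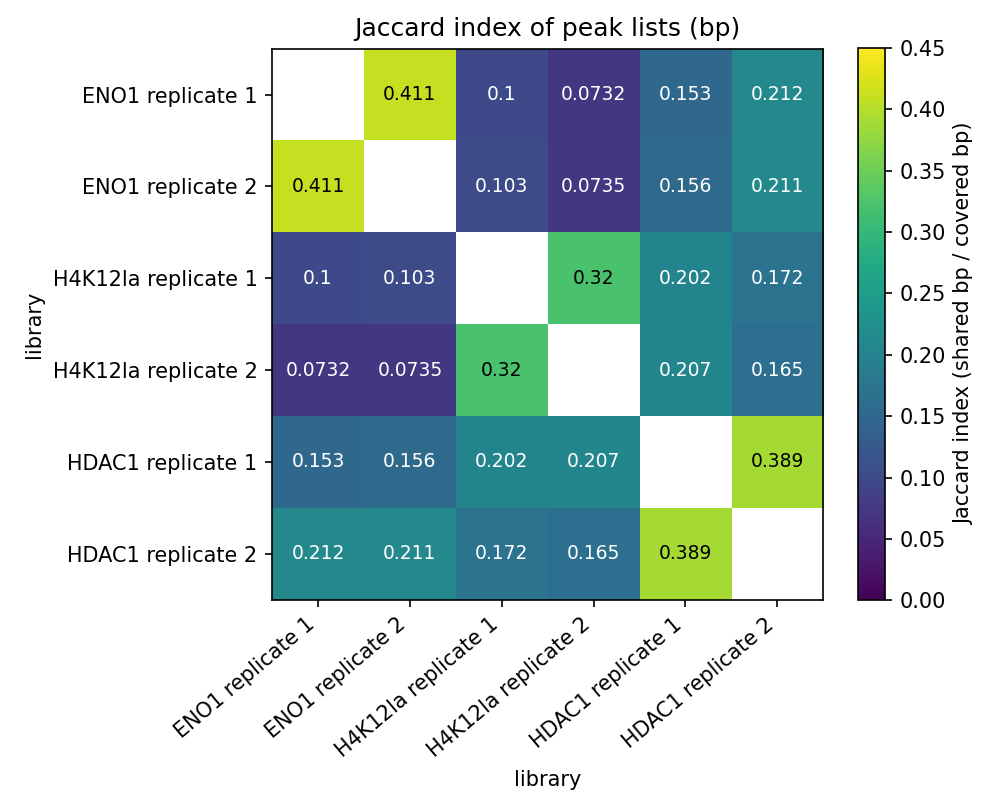
Jaccard index (shared base pairs as a part of covered base pairs, colour scale) for each pair of the 6 libraries, which stand on both axes. The same-target pairs reach 0.411, 0.320 and 0.389, and the highest different-target pair, ENO1 replicate 1 with HDAC1 replicate 2, reaches 0.212.

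Gene-end peaks present in both replicates were found at 13 of 19862 protein-coding genes for ENO1, 2077 for H4K12la and 1626 for HDAC1. Replicates 1 and 2 alone gave 33 and 20 genes for ENO1, 2675 and 3877 for H4K12la, and 2948 and 2006 for HDAC1; within 500 bp of gene ends ENO1 had 7 genes, and at -log10 q of 5 or more H4K12la had 1214. The highest ENO1 values were at TMEM216 (chromosome 11, 61392587 to 61398846), which encodes a membrane protein of the ciliary transition zone, at 9.72-fold and 23.1-fold in replicates 1 and 2. OR2T1, an olfactory receptor gene (chromosome 1, 248403048 to 248408020), followed at 10.2-fold and 8.85-fold, and CCDC200 (chromosome 17, 43221417 to 43231269) at 10.5-fold and 8.57-fold. These genes also carried H4K12la (TMEM216, 20.7-fold and 21.5-fold) and HDAC1 (TMEM216, 23.9-fold and 25.7-fold) in both replicates. Several of the other ENO1 genes belong to families of near-identical copies between which reads may be shared: USP17L11 (5.22-fold and 5.95-fold), a deubiquitinase-like gene, TAF11L7 (4.31-fold and 5.23-fold), TAF11L3 (5.20-fold and 3.43-fold) and NPIPB5 (4.83-fold and 4.07-fold). WDR81, whose product acts in endosomal trafficking, had 5.18-fold and 4.38-fold, LOC107987020 5.66-fold and 4.39-fold, and LOC124902048 3.47-fold and 3.44-fold.

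Beyond those genes, H4K12la was highest at IFT70A, a gene of intraflagellar transport (7.63-fold and 7.28-fold), and at TBC1D32, which acts in cilia (7.18-fold and 7.47-fold). A peak shared by the neighbouring COMMD6 and UCHL3, the latter a ubiquitin hydrolase gene, reached 6.71-fold and 6.50-fold. MMADHC, which acts in cobalamin metabolism, had 6.48-fold and 6.92-fold, SEC23B, a coat protein gene of vesicles leaving the endoplasmic reticulum, 6.94-fold and 6.45-fold, and MIGA1, whose product acts in mitochondrial fusion, 6.38-fold and 6.95-fold. HDAC1 was highest at FAM86B1 (13.0-fold and 13.5-fold), NT5C3A, a pyrimidine nucleotidase gene (9.71-fold and 9.72-fold), and LRIF1, whose product binds heterochromatin proteins (9.29-fold and 9.48-fold). RAP2A, a small GTPase gene, had 9.0-fold and 9.98-fold of HDAC1, KDM4A, a histone demethylase gene, 9.79-fold and 8.73-fold, FAM168A 8.72-fold and 9.16-fold, and FARP2, a guanine exchange factor gene, 8.57-fold and 9.76-fold. The gene ENO1 itself (chromosome 1, 8861000 to 8878686) carried HDAC1 at 4.51-fold and 4.90-fold and no gene-end peak of ENO1 or H4K12la in any library. MYC, the growth-driving transcription factor, likewise had only HDAC1 (4.54-fold and 3.27-fold). LDHA, which makes lactate from pyruvate, and HDAC1 had a gene-end peak only of H4K12la in replicate 2 (3.02-fold and 3.08-fold).

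Overlap between targets was asked next, since the series concerns ENO1 and HDAC1 acting together on lactylation. H4K12la and HDAC1 shared 631 genes, 30.4% of the H4K12la genes and 38.8% of the HDAC1 genes, while 1446 genes had only H4K12la of the pair and 995 only HDAC1 (odds ratio 7.36, 95% interval 6.56 to 8.26, Fisher's exact p = 2.35e-226). Of the 13 ENO1 genes, 11 carried HDAC1 (odds ratio 62.1, 13.5 to 577, Fisher's exact p = 7.17e-11). H4K12la was present at 6 of them, TMEM216, OR2T1, CCDC200, TAF11L3, NPIPB5 and LOC107987020, all of which also carried HDAC1 (odds ratio 7.36, 2.04 to 25.6, Fisher's exact p = 0.00116). TAF11L7 had H4K12la (4.63-fold) and HDAC1 (4.52-fold) in replicate 1 only. All 3 tests were two-sided, and genes, several of them in multicopy families, are not independent replicates. Without a control library analysed here, these overlaps cannot tell shared occupancy from sequence that every antibody recovers. The ENO1 overlap with H4K12la did not pass within 500 bp of gene ends (odds ratio 3.83, Fisher's exact p = 0.136), nor among genes with a gene-end peak in any library (odds ratio 1.53, Fisher's exact p = 0.564). Against that same background the odds ratio fell to 1.19 for H4K12la with HDAC1 (Fisher's exact p = 0.00457) and to 14.1 for ENO1 with HDAC1 (Fisher's exact p = 3.66e-05). That background leaves out most genes without either mark by construction, which lowers the odds ratios. The fall therefore does not show that the overlaps were weaker.

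At the level of regions, the overlaps with ENO1 lay mostly far from protein-coding genes, while that of H4K12la with HDAC1 was spread more evenly. Of the 768 ENO1 regions, 638 (83.1%) overlapped an HDAC1 region and 436 (56.8%) an H4K12la region, against random means of 0.194% and 0.203%. Both at once were overlapped by 427 ENO1 regions, of which 311 (72.8%) lay over 50 kb from any protein-coding gene and 8 at gene ends. H4K12la regions overlapped HDAC1 in 1246 of 3561 cases (35.0%) and ENO1 in 440 (12.4%); of the 1246, 37.8% lay at gene ends and 33.6% over 50 kb from a gene. HDAC1 regions overlapped H4K12la in 40.3% and ENO1 in 20.8% of 3089 cases. Each overlap exceeded its random placements (one-sided permutation p = 0.001, the smallest possible). These overlap tests of regions between targets were not among the tests fixed beforehand.

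H4K12la peaks were stronger where ENO1 regions lay and, by a margin that varied with the peaks used, where HDAC1 regions lay. In H4K12la replicate 1, the 532 peaks that overlapped an ENO1 region had a median of 6.55-fold and the other 4927 a median of 3.95-fold, a difference of 2.61. Replicate 2 gave 6.35-fold for 535 peaks and 3.98-fold for 7033, a difference of 2.37. With HDAC1 regions the medians were 4.35-fold (1484 peaks) against 3.94-fold (3975 peaks) in replicate 1, and 4.42-fold (1778 peaks) against 3.96-fold (5790 peaks) in replicate 2. All of these differences passed a two-sided permutation test (p = 1e-05, the smallest that 100000 resamples can give), with peaks as the units. With equal numbers of strongest peaks per library, the differences were 2.67 and 2.78 with ENO1 and 2.33 and 1.92 with HDAC1 (permutation p = 1e-05 each, the smallest possible). That setting also changed which peaks were compared. Peaks over 50 kb from genes made up 37.1% and 29.1% of the shortened H4K12la lists, against 17.5% and 12.9% of the full lists. Of the H4K12la regions overlapping ENO1, 73.0% lay over 50 kb from a gene, as did 33.6% of those overlapping HDAC1. Among H4K12la peaks at gene ends, chosen after the data were seen, the difference with HDAC1 turned to -0.0894 in replicate 1 (permutation p = 0.0363) and -0.0124 in replicate 2 (permutation p = 0.794), and that with ENO1 was 0.682 over 7 peaks (permutation p = 0.0469) and 0.492 over 11 peaks (permutation p = 0.104).

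**Figure D3:**
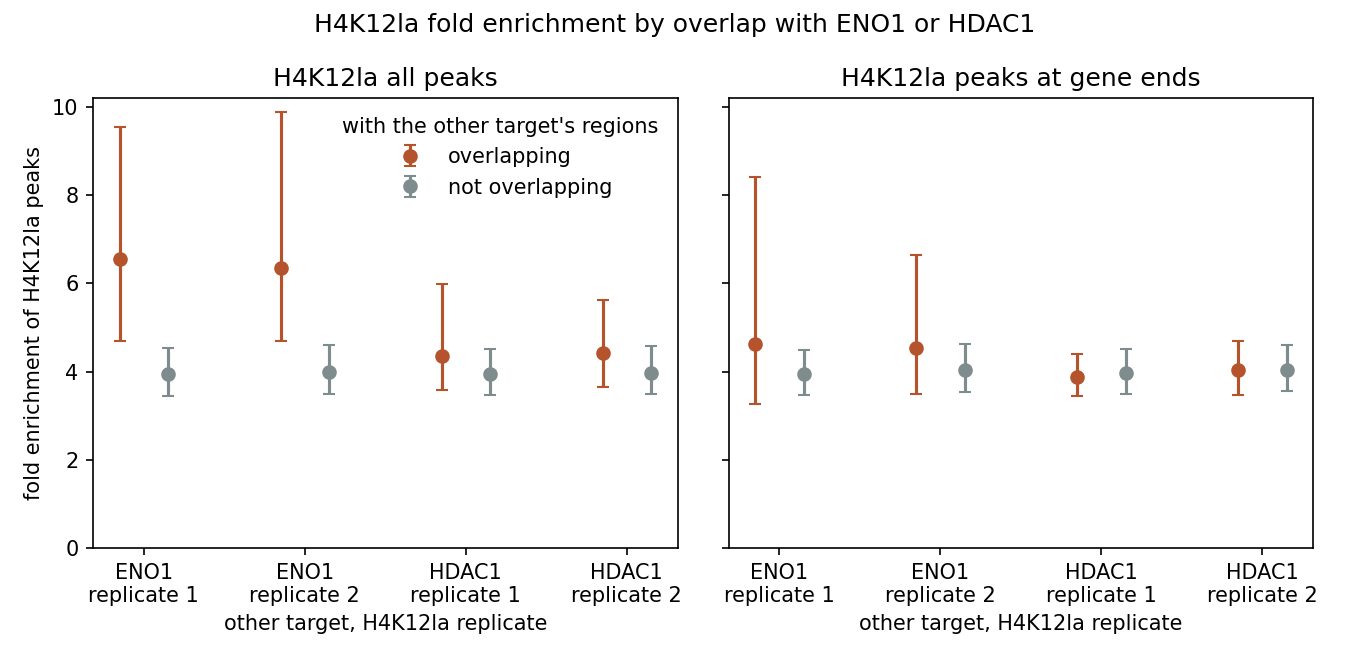
Fold enrichment of H4K12la peaks (vertical axis, peak caller's ratio) that overlap or do not overlap ENO1 or HDAC1 regions, for each H4K12la replicate, over all peaks and over peaks at gene ends; points are medians and bars run from the lower to the upper quartile. Over all peaks the medians with ENO1 are 6.55 and 6.35 against 3.95 and 3.98, and at gene ends the medians with HDAC1 are 3.87 and 4.03 against 3.96 and 4.04.

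The 29 gene lists asked which functions carried each target. H4K12la lay at mitochondrial ribosomal protein, oxidative phosphorylation and aminoacyl-tRNA synthetase genes more often than at other protein-coding genes, 10.4% of which carried it. It marked 20 of 74 mitochondrial ribosomal protein genes (27.0%), among them MRPL3 (4.77-fold and 5.64-fold), MRPS33 (5.24-fold and 4.75-fold), MRPL50 and MRPL52. It marked 17 of 69 oxidative phosphorylation genes (24.6%), with UQCRB of complex III (6.06-fold and 4.88-fold), NDUFB1 of complex I (4.69-fold and 5.74-fold) and ATP5MC3 of the ATP synthase (4.61-fold and 7.16-fold). It marked 10 of 35 aminoacyl-tRNA synthetase genes (28.6%), which charge tRNAs with amino acids, with GARS1 (5.37-fold and 5.70-fold) and LARS2 (5.18-fold and 4.70-fold). The odds ratios were 3.19 (95% interval 1.81 to 5.43, adjusted p = 0.00123), 2.81 (1.52 to 4.96, adjusted p = 0.00572) and 3.44 (1.47 to 7.42, adjusted p = 0.0191), by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 87 tests of 29 lists and 3 targets. Olfactory receptor genes, not used in liver cells, carried H4K12la at 1 of 389 members (adjusted exact p = 1.11e-15), and keratin-associated protein genes at 0 of 94 (adjusted exact p = 0.00123).

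HDAC1 lay at histone, splicing, chaperone and Wnt target genes more often than at other genes, and at 8.19% of all protein-coding genes. It marked 16 of 69 replication-dependent histone genes (23.2%), with 10 regions shared by both replicates, such as H2AC11 and H2BC11 under a shared peak (6.72-fold and 5.59-fold) and H1-4 beside H2BC5 (4.19-fold and 3.99-fold). It marked 14 of 58 splicing factor genes (24.1%), with SF3B6 (7.46-fold and 8.13-fold), HNRNPD (8.01-fold and 7.21-fold) and HNRNPK (6.03-fold and 5.39-fold). Of 27 genes of the unfolded protein and heat shock response it marked 9 (33.3%), with PDIA4, a protein disulfide isomerase gene (7.18-fold and 8.96-fold), the chaperonin pair HSPD1 and HSPE1 under a shared peak (7.73-fold and 6.63-fold), and HSPH1 (7.68-fold and 6.44-fold). Of 17 Wnt targets it marked 6 (35.3%), with TNFRSF19 (5.51-fold and 4.90-fold), the Wnt antagonist DKK1 (4.49-fold and 4.91-fold), the stem cell receptor LGR5 (4.44-fold and 3.70-fold) and SP5 (3.52-fold and 4.36-fold). Aminoacyl-tRNA synthetase genes carried it at 8 of 35 members (22.9%), with WARS2 (6.30-fold and 7.20-fold) and EARS2 (5.34-fold and 5.22-fold). In that order the odds ratios were 3.41 (1.81 to 6.07), 3.59 (1.81 to 6.69), 5.63 (2.23 to 13.2), 6.14 (1.86 to 18.1) and 3.33 (1.31 to 7.56), and the adjusted p values 0.00194, 0.00242, 0.00242, 0.0146 and 0.0458. Olfactory receptor genes carried HDAC1 at 1 of 389 members (adjusted exact p = 7.78e-12) and keratin-associated protein genes at 0 of 94 (adjusted exact p = 0.00553).

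Set directly against each other among genes carrying only 1 of the pair, in a test added after the list results were seen, only the histone genes differed between H4K12la and HDAC1 over 26 lists. HDAC1 alone was at 16 of them and H4K12la alone at 2, H2AC15 (4.91-fold and 3.45-fold) and H2BC15 (4.91-fold and 2.93-fold), giving an odds ratio of 11.8 (2.76 to 106, Fisher's exact p = 3.18e-05, adjusted p = 8.28e-04). Within strata of gene density that odds ratio was 3.45 (0.835 to 14.3, p = 0.0538, Cochran-Mantel-Haenszel chi-square test). Mitochondrial ribosomal protein genes, with H4K12la alone at 18 and HDAC1 alone at 3, did not pass (odds ratio 0.240, adjusted exact p = 0.172), nor did oxidative phosphorylation genes (11 and 4, odds ratio 0.527, adjusted exact p = 0.622).

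**Figure D4:**
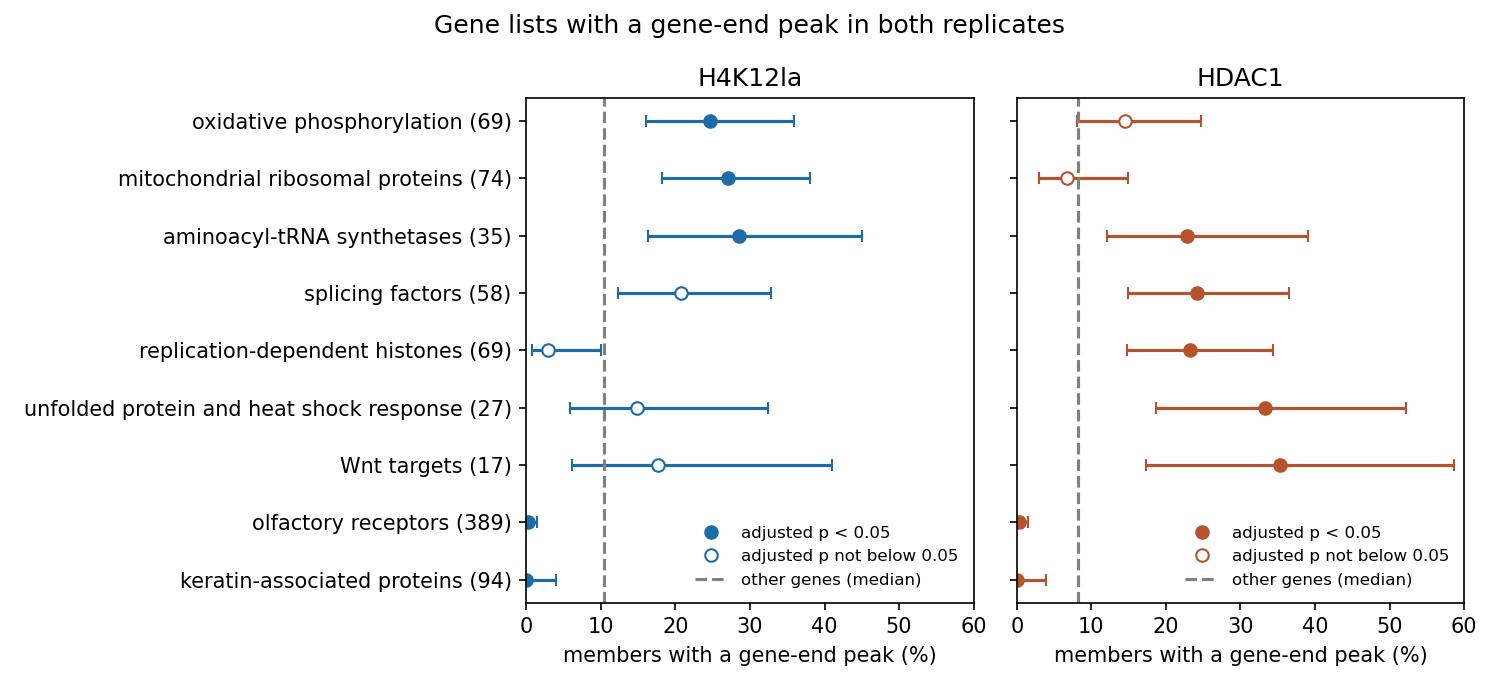
Percent of list members with a gene-end peak in both replicates (horizontal axis) for H4K12la and HDAC1, with the number of members in parentheses; points are shares, bars Wilson 95% intervals, filled points have an adjusted p under 0.05 and the dashed line is the median share of other genes. HDAC1 reaches 35.3% of Wnt targets and 23.2% of histone genes, and H4K12la 27.0% of mitochondrial ribosomal protein genes.

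These list results depended on what the genes were compared with. Among genes with a gene-end peak in any of the 6 libraries, none of the lists that stood above other genes passed: the odds ratios ran from 1.46 for aminoacyl-tRNA synthetases with HDAC1 to 3.84 for Wnt targets, the lowest adjusted exact p was 0.161 for histone genes with HDAC1. The lists below other genes lost their calls there too: olfactory receptors had odds ratios of 0.892 with H4K12la and 1.28 with HDAC1, and keratin-associated proteins 0 with both (adjusted exact p = 1 each), while histone genes fell below other genes with H4K12la (odds ratio 0.122, adjusted exact p = 0.0198). That background leaves out most unmarked genes by construction. A gene can enter it through another target's peak alone, so the histone value does not by itself show depletion of H4K12la. At -log10 q of 5 or more, the splicing factor and the unfolded protein and heat shock lists still passed for HDAC1, and no list above other genes passed for H4K12la, with odds ratios of 2.02 for oxidative phosphorylation, 2.41 for mitochondrial ribosomal proteins and 2.57 for aminoacyl-tRNA synthetases. For HDAC1 there, aminoacyl-tRNA synthetases had 2.48, histones 1.95 and Wnt targets 3.19 without passing, and keratin-associated proteins did not pass for either target (adjusted exact p = 0.0637 each). With equal numbers of strongest peaks only the unfolded protein and heat shock list passed (odds ratio 15.4), and no Wnt target carried HDAC1 (odds ratio 0). With those fewer peaks, the odds ratios of splicing factors (3.67) and aminoacyl-tRNA synthetases (4.07) with HDAC1, and of aminoacyl-tRNA synthetases (5.19) and oxidative phosphorylation (2.55) with H4K12la, did not pass, while mitochondrial ribosomal proteins with H4K12la fell to 1.16 and histones with HDAC1 to 2.0. The histone list with HDAC1 and the oxidative phosphorylation list with H4K12la did not pass when replicate peaks had to overlap by 50% of each other (odds ratio 2.29, adjusted exact p = 0.137, and odds ratio 2.44, adjusted exact p = 0.0746). Nor did aminoacyl-tRNA synthetases with HDAC1 (odds ratio 3.38, adjusted exact p = 0.0657). That list lost its HDAC1 call in 5 of 12 alternatives, among them whole genes, a setting added after the data were seen. Another of the 12, limited to peaks near genes, keeps every gene-end peak and so could not change a list call.

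Other lists did not pass the adjusted threshold in the main setting. Cell cycle and p53 target genes passed with HDAC1 in either single replicate and with peaks of either replicate. They did not pass at a stricter q or with equal numbers of strongest peaks. Some further lists passed outside the main setting. Translation initiation and splicing factors with H4K12la, and citric acid cycle genes with HDAC1, did so in replicate 2 alone and with peaks of either replicate. Hypoxia and cholesterol genes with HDAC1 did so in replicate 1 alone and with peaks of either replicate. Glycolysis and lactate genes carried H4K12la at 3 of 23 members (adjusted exact p = 1), PFKM (4.66-fold and 4.05-fold), GPI (3.03-fold and 3.35-fold) and the lactate transporter SLC16A3 (2.95-fold and 2.60-fold). HDAC1 lay at 3 of the 23 (adjusted exact p = 0.913), GPI (7.45-fold and 5.71-fold), ALDOA (3.69-fold and 2.79-fold) and ENO1. Cell cycle and DNA replication genes carried HDAC1 at 8 of 36 members, with CDK2 (7.23-fold and 6.28-fold) and CDC45 (6.75-fold and 6.07-fold), and H4K12la at 3 of 36 (adjusted exact p = 0.0505 for HDAC1 and 1 for H4K12la). Citric acid cycle genes carried HDAC1 at 6 of 25 members, with MDH1 (8.19-fold and 6.45-fold), and H4K12la at 5 (adjusted exact p = 0.0800 and 0.479). Translation initiation factor genes, a list that also holds EIF2AK kinase genes, carried H4K12la at 12 of 56 members and HDAC1 at 9 (adjusted exact p = 0.0800 and 0.188). Proteasome subunit genes carried them at 8 and 5 of 39 (adjusted exact p = 0.234 and 0.585), and cytosolic ribosomal protein genes at 5 and 10 of 77 (0.799 and 0.435). Splicing factor genes carried H4K12la at 12 of 58 members (adjusted exact p = 0.0929) and histone genes at 2 of 69 (adjusted exact p = 0.188).

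Liver genes were marked at rates that did not pass the test either. Secreted liver protein genes carried H4K12la at 1 of 31 members, ORM1 (4.24-fold and 3.42-fold), and HDAC1 at none (adjusted exact p = 0.585 and 0.479). Liver transcription factor genes carried H4K12la at 3 of 23, HNF4G (3.67-fold and 4.27-fold), HNF4A (3.55-fold and 3.34-fold) and FOXA1 (3.31-fold and 2.77-fold), and HDAC1 at 2, ATF5 and CEBPB (adjusted exact p = 1 each). Liver metabolic enzyme genes carried H4K12la at 3 of 29, among them ASS1 of the urea cycle (5.33-fold and 4.57-fold), and HDAC1 at 1, HPD (adjusted exact p = 1 each). Cholesterol and fatty acid synthesis genes carried HDAC1 at 6 of 31, with LSS (5.79-fold and 7.83-fold), and H4K12la at 2 (adjusted exact p = 0.171 and 1). Genes for HDAC1 complexes carried H4K12la at 2 of 27 members, HDAC2 (3.54-fold and 4.42-fold) and RBBP4, and HDAC1 at 5, with ARID4B (8.43-fold and 5.94-fold; adjusted exact p = 1 and 0.246). The list of lactyl and acetyl enzymes also holds BRD2, a gene for a reader of acetyl marks. Members of that list carried H4K12la at 3 of 23, BRD2, EP300 and HDAC2, and HDAC1 at 2, KAT6A and KAT8 (adjusted exact p = 1 each).

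Of the stress lists, hypoxia genes carried H4K12la and HDAC1 at 3 and 5 of 23 members, with ANKRD37 (4.84-fold and 4.78-fold of H4K12la; adjusted exact p = 1 and 0.171). Those of p53 targets were 2 and 5 of 22, with TP53I3 (8.40-fold and 8.97-fold of HDAC1; adjusted exact p = 1 and 0.152). Autophagy and lysosome genes had 3 and 4 of 24 (adjusted exact p = 1 and 0.414), and ferroptosis and redox genes 3 and 3 of 21 (adjusted exact p = 0.988 and 0.585). Immediate early genes had 0 and 3 of 21, with JUN (4.30-fold and 4.08-fold of HDAC1) and EGR1 (4.35-fold and 4.21-fold of HDAC1; adjusted exact p = 0.478 and 0.585). H4K12la lay at 4 of 27 genes of the unfolded protein and heat shock response and at 3 of 17 Wnt targets (adjusted exact p = 1 and 0.897), and HDAC1 at 10 of 69 oxidative phosphorylation and 5 of 74 mitochondrial ribosomal protein genes (adjusted exact p = 0.254 and 1). The lists for other cell types did not pass either: extracellular matrix and mesenchymal genes at 2 and 1 of 24 (adjusted exact p = 1 each), blood and immune genes at 1 and 0 of 30 (0.810 and 0.479), and neuron and muscle genes at 0 and 0 of 32 (0.254 and 0.360). ENO1 had a gene-end peak at a single list member, OR2T1, and by Fisher's exact test none of its 29 lists passed, with 0 also at an unadjusted p under 0.05.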

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

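The tests of ENO1 regions found in all or in none of the other libraries, the direct comparison of gene lists between H4K12la and HDAC1, and the restrictions of H4K12la peaks to gene ends and to 50 kb from genes were chosen after the results were seen, and the grouping of genes by shared region was corrected after its first result was seen.

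ENO1 regions lay far from genes, 74.2% of them over 50 kb from a protein-coding gene. Occupancy by ENO1 alone is argued against by the 3.65% of regions with no peak in the 4 other libraries. The smaller number of ENO1 peaks is argued against as the whole cause, since H4K12la and HDAC1 lists of equal length still had 28.9% and 26.6% of their regions at gene ends, 13.5 and 12.4 times the ENO1 share of 2.15% from lists of that length. Sequence that every antibody recovers stays open and is consistent with the 55.7% of ENO1 regions that had a peak in all 4 H4K12la and HDAC1 libraries. Occupancy shared by ENO1, HDAC1 and H4K12la would give such overlap too and stays open and untested, as does repeated sequence, since no control library or genome sequence was used here.

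Histone genes differed between HDAC1 and H4K12la in the odds of carrying only 1 of them (odds ratio 11.8), and chromosome 19 genes leaned the same way (odds ratio 24.4, 11.9 to 58.1). On chromosome 19 the lean came from scarce H4K12la, at 1.06% of genes against 10.5% of all protein-coding genes. HDAC1 lay there at 8.94%, near its 8.19% of all protein-coding genes. Neighbouring genes under a shared peak are argued against as the whole cause for the histone genes. With 1 gene per group of genes sharing a region, 11 had only HDAC1 and 1 only H4K12la (Fisher's exact p = 2.44e-04). Within length strata the histone odds ratio fell from 11.8 to 5.74 (Cochran-Mantel-Haenszel chi-square p = 0.00892), so gene length may account for part of it. Length differences inside a stratum were not removed, so this test cannot exclude gene length as the whole cause. Gene-dense sequence may account for the histone result, whose odds ratio moved to 3.45 (0.835 to 14.3, Cochran-Mantel-Haenszel chi-square p = 0.0538) within density strata, a call that ended because the ratio shrank and its interval stayed wide, and outside chromosome 19 HDAC1-only genes had 14 neighbours in the median and H4K12la-only genes 7, a difference of 7 (permutation p = 1e-05, the smallest possible). For chromosome 19 itself the odds ratio fell from 24.4 to 8.12 within density strata (3.78 to 17.4, Cochran-Mantel-Haenszel chi-square p = 8.04e-10). Gene density may thus account for part of it. Chromosome 19 genes had 30 neighbours in the median, against 12 for all genes. Density differences inside a stratum were not removed, so this test cannot exclude gene density as the whole cause. A difference between the targets themselves and the base composition of gene-dense sequence stay open and were not tested.

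H4K12la peaks overlapping HDAC1 regions were stronger over all peaks, by 0.406 and 0.462 in median fold. Peaks over 50 kb from genes are argued against as the whole cause in replicate 2, where the difference without them was 0.188 (1255 peaks with overlap and 5337 without, permutation p = 1e-05, the smallest possible), but may account for replicate 1, where it was 0.0394 (933 and 3573 peaks, permutation p = 0.244). Peaks away from gene ends, near or far, may account for both, because among gene-end peaks the differences were -0.0894 (512 peaks with overlap and 1725 without, permutation p = 0.0363) and -0.0124 (738 and 2578 peaks, permutation p = 0.794). No biological explanation was tested for this pattern.

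Outside the chromosomes used, each list held peaks on unplaced sequences and the mitochondrial genome, data that no comparison above used: 226 and 206 for ENO1, 193 and 205 for H4K12la, and 252 and 235 for HDAC1, of which 5 to 7 per library were mitochondrial. They made up 12.4% and 14.8% of the ENO1 lists, 3.41% and 2.64% of the H4K12la lists, and 4.21% and 4.89% of the HDAC1 lists.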

How the results depend on the processing

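The settings limited to peaks near genes, to whole genes and to H4K12la peaks at gene ends were chosen after the data were seen; all others were planned. Of the values that answer a comparison, 188 kept their call or size (5 of them the Jaccard mean, whose test cannot pass 0.05), 36 moved, 4 fell short of the threshold and 3 reversed. Of those for single genes and lists 368, 48, 33 and 2 did. The setting limited to peaks near genes keeps every gene-end peak by construction. Gene counts, overlaps of occupied genes, list calls and gene folds therefore could not change in it, but were counted as kept. The cause was not tested except where a setting's construction gives it. For single genes these counts say little about robustness. A fold was counted as kept if it moved by no more than the SD of its replicates. With 1 replicate left out, that outcome was fixed by which replicate had the higher fold. A setting that only removes peaks returns the same fold unless the strongest gene-end peak is lost, and genes left without a peak were not counted. The Jaccard mean ran from 0.340 to 0.449. Replicate overlap ran from 52.9% to 72.6% with its calls kept, as were those of the gene-end shares of H4K12la (28.9% to 56.8%, and 71.2% over whole genes) and HDAC1 (26.6% to 59.2%, and 57.5% over whole genes) and of the overlaps of H4K12la with HDAC1 (odds ratio 1.19 to 9.63) and of ENO1 with HDAC1 (14.1 to 70.4). At -log10 q of 5 or more, H4K12la had 1214 genes and 0 lists above and 1 below other genes, and HDAC1 2 and 1. Equal numbers of strongest peaks, which leave fewer peaks, gave 231 and 293 genes and 0 lists above and 0 below for H4K12la, 1 and 0 for HDAC1, and an odds ratio of 0 for Wnt targets with HDAC1. Peaks of either replicate gave 40, 4475 and 3328 genes for ENO1, H4K12la and HDAC1 and 8 lists above and 4 below for H4K12la and 14 and 4 for HDAC1. Without replicate 1 or 2, genes ranged from 20 to 33 for ENO1, 2675 to 3877 for H4K12la and 2006 to 2948 for HDAC1, and lists above from 3 to 7 for H4K12la and from 9 to 12 for HDAC1. A 500 bp window gave 7 ENO1 genes and an odds ratio of 3.83 (Fisher's exact p = 0.136) for ENO1 with H4K12la, and 2500 bp gave 24 genes. With only genes that had a peak in any library as background, that odds ratio was 1.53 (Fisher's exact p = 0.564), lists above and below were 0 and 1 for H4K12la and 0 and 0 for HDAC1, the 1 being histone genes, which were not called before, and olfactory receptors turned to 1.28 with HDAC1 and 0.892 with H4K12la; most unmarked genes are then left out by construction. Near genes only, the ENO1 gene-end share was 7.58%, above random placement (permutation p = 0.018). The placements of all targets in that setting still covered whole chromosomes, so its gene-end tests cannot show gathering at gene ends. The HDAC1 difference near genes was 0.0394 in H4K12la replicate 1 (permutation p = 0.244) and 0.188 in replicate 2 (permutation p = 1e-05, the smallest possible). Whole genes gave 91 genes for ENO1. At gene ends only, the HDAC1 differences were -0.0894 and -0.0124 and the ENO1 difference in replicate 2 was 0.492 (permutation p = 0.104). The replicate numbers gave little sign of pairing the libraries: replicate differences correlated at 0.00292, -0.0250 and 0.0454 between targets over 5782 genes. These differences rest on presence of peaks alone, so they cannot exclude that libraries of the same number shared a culture or batch. With the replicate number as a block, which counts each gene once per replicate so that its p values are too small, H4K12la had 7 lists above and 6 below and HDAC1 16 and 4, the overlaps were 5.37, 21.3 and 7.46 for ENO1 with H4K12la, ENO1 with HDAC1 and H4K12la with HDAC1, the differences in median fold were 2.14 and 2.10 with ENO1 and 0.240 and 0.468 with HDAC1, and no call of an overlap or a median changed. Of named genes, 34 of 100 for H4K12la and 15 of 104 for HDAC1 lost their peak at the stricter q, and 74 and 70 with equal numbers; 5 of 10 for ENO1 did so at 500 bp. The all-sequences setting cannot move gene counts. Alternatives on repeat sequence, transcript starts and motifs were not run, and unknown depth limits every comparison of list lengths.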

Other observations

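The comparisons by chromosome, gene class and gene length were chosen after the data were seen, as were the zinc finger groups.

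Chromosome 19 leaned most to HDAC1, through scarce H4K12la rather than more HDAC1. Of its 1410 protein-coding genes, 1.06% carried H4K12la in both replicates and 8.94% HDAC1, against 10.5% and 8.19% of all protein-coding genes. There 8 genes carried only H4K12la and 119 only HDAC1 (odds ratio 24.4, 11.9 to 58.1, two-sided Fisher's exact test, adjusted p = 3.74e-37 over 24 chromosomes). GPI, the second enzyme of glycolysis, is among the genes there with both (3.03-fold and 3.35-fold of H4K12la, 7.45-fold and 5.71-fold of HDAC1). The zinc finger genes of chromosome 19, 246 in number, had 13 with only HDAC1 and 5 with only H4K12la (odds ratio 3.81, 1.27 to 13.7, adjusted p = 0.0117 over 3 groups, two-sided Fisher's exact tests), and the other 1164 genes 106 and 3 (odds ratio 57.3, 19 to 283, adjusted exact p = 2.26e-38). HDAC1 lay at 9.45% of those 1164 genes and at 8.11% of the remaining protein-coding genes (Fisher's exact p = 0.110). For H4K12la these shares were 0.601% and 11.1% (Fisher's exact p = 9.65e-47). At the 246 zinc finger genes HDAC1 reached 6.50% against 8.21% (Fisher's exact p = 0.412), and H4K12la 3.25% against 10.5% (Fisher's exact p = 3.57e-05). All 509 zinc finger genes together showed no such lean, with 23 and 27 (odds ratio 1.24, 0.677 to 2.27, adjusted exact p = 0.469). Chromosomes 16 (odds ratio 1.92, adjusted exact p = 0.0146) and 17 (1.93, adjusted p = 0.00319) leaned to HDAC1 as well. Chromosome X was low in both, with 1.30% of 848 genes carrying H4K12la and 2.0% HDAC1 (odds ratio 2.44, adjusted exact p = 0.109). Chromosome 2 leaned to H4K12la, with 22.9% of genes carrying it and 12.9% HDAC1 (odds ratio 0.481, adjusted exact p = 3.17e-06), and so did chromosomes 10 (0.414, adjusted p = 1.14e-04), 4 (0.520, adjusted p = 0.0146) and 5 (0.556, adjusted p = 0.0146).

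Transfer RNA genes, transcribed by RNA polymerase III, carried HDAC1 at 44 of 429 (10.3%) and H4K12la at 12 (2.80%), with 38 genes carrying only HDAC1 and 6 only H4K12la (two-sided exact McNemar test, p = 9.43e-07); many are near-identical copies in clusters and are not independent. ENO1 regions touched 0 of the tRNA genes but 44 of 15416 pseudogenes, more entries than its 13 of 19862 protein-coding genes. Genes with only H4K12la were long, with a median of 45.7 kb over 1446 genes, against 22.5 kb over the 995 with only HDAC1, 36.6 kb over the 631 with both and 24.5 kb over all protein-coding genes.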
